A study of Mus musculus with 9 samples.

How the data were processed

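The series holds 9 RNA sequencing libraries from the cerebral cortex of untreated adult mice of the Abcb1a-TRAP line ES3026, in 3 groups of 3: ribosome-bound RNA purified with antibodies against the tag and extracted by investigator ES, the same fraction extracted by investigator JL, and input RNA extracted by JL. Per the labels' protocols, the cortex was homogenised, tagged polysomes were captured on magnetic beads, and RNA was purified with a column kit. Per the submitters' processing notes, reads were aligned with STAR 2.0.0e to the mouse genome mm10 and counted with HTSeq. The gene annotation, the strand setting and any filter are not given in the sources used here, so reads of a gene and of an overlapping antisense gene cannot be told apart.

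The deposited values are raw read counts per gene, 1 file per library, with 32531 gene rows. Of the row names, 23155 are symbols of the GENCODE M21 annotation used here for positions (mm10), 24207 are symbols or synonyms, and 8381 are sequence accessions. Mitochondrially encoded genes were not analysed here. HTSeq's special rows and a row for unknown genes were left out of library sizes and tests. The share without a feature was 18.0 ± 1.03% in the ES IPs, 23.5 ± 0.771% in the JL IPs and 19.3 ± 0.503% in the inputs, and the ambiguous share 2.48 ± 0.0507%, 2.09 ± 0.0460% and 10.8 ± 0.520%. Alignments counted as not unique came to 1.13 ± 0.258, 1.90 ± 0.132 and 0.626 ± 0.0135 per gene count. Reads that fit several places entered no gene, so genes with near-identical copies are undercounted. The ribosomal RNA precursor row Rn45s held 8.74 ± 3.04%, 16.9 ± 1.09% and 5.10 ± 0.236% of gene counts (mean ± SD, n = 3). No column of the files was left unmapped.

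Gene counts per library ran from 31987470 to 46598478. A count of 3 corresponds to 0.0689 ± 0.00370 CPM in the ES IPs, 0.0884 ± 0.00789 in the JL IPs and 0.0668 ± 0.00304 in the inputs, and levels near these carry large counting error. Chi-square statistics between replicate counts were 7.84 to 10.2 per degree of freedom in the inputs, 31.0 to 41.3 in the JL IPs and 79.8 to 253 in the ES IPs, so no 2 files were repeat counts of 1 library, and each was counted as 1 replicate; this does not show that they came from separate mice. Pearson correlations of log2 CPM lay between 0.958 and 0.993 within groups, 0.765 and 0.787 between JL IP and input, 0.886 and 0.921 between ES IP and input, and 0.865 and 0.898 between ES and JL IPs.

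Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM factors, estimateDisp, glmQLFit and glmQLFTest, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. The 3 comparisons were JL IP against JL input, ES IP against JL IP, and the 6 IP libraries against the 3 inputs; each fit held only the libraries compared. JL input serves 2 of the comparisons and JL IP all 3, so the comparisons are not independent. The standard error is the log2 fold change divided by the square root of F. On simulated counts with the real means and spread, the test recovered 63% of 2-fold and 84% of 4-fold changes for JL IP against input (16805 genes), 52% and 88% for ES against JL IP (15896 genes), and 0% and 13% for all IP against input (17302 genes). Only 100 genes were changed at each fold. With so few, the adjustment sets a stricter cutoff than in the real data, so these shares can understate recovery there.

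There were 28 gene lists, fixed before the data were examined: markers of endothelium in general, barrier transporters, tight junctions, Wnt and Norrin signalling, arteries, veins and leukocyte adhesion, peripheral endothelium, basement membrane, pericytes, smooth muscle, fibroblasts, astrocytes, neurons, excitatory and inhibitory neurons, oligodendrocytes and their precursors, microglia, blood cells, choroid plexus and ependyma, immediate early and stress genes, interferon response, nuclear-retained RNA, cell cycle, sex-linked genes, ribosomal proteins, oxidative phosphorylation and mitochondrially encoded genes, a list left empty here. Lists with at least 4 tested genes were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera called 19 of 26 lists for JL IP against input, 13 of 27 for ES against JL IP and 20 of 27 for all IP against input; with an estimated correlation 5, 2 and 0 held. The rotation test fry, run as an alternative, called 24, 19 and 17. Adjusted over the list alone, the counts were 32 higher of 32 pan-endothelial genes and 17 lower of 17 neuron genes for JL IP against input, and 32 lower and 17 higher for ES against JL IP.

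Named genes followed a rule fixed before the data were examined: Abcb1a and Rpl10a always; the 10 largest and 10 smallest log2 fold changes (5 and 5 for all IP) among genes with adjusted p under 0.05, a mean of at least 10 CPM in the higher group and no overlap between groups, leaving out predicted genes, pseudogenes and small RNAs; for each list the 2 highest members and those with the largest and smallest change; and members that moved against their list. Some genes this rule names are not reported here. Alternatives were other scalings (RLE, upper quartile, library size), no low-count filter or a CPM of at least 1 in 3 libraries, DESeq2 1.42.0, limma-voom, legacy robust quasi-likelihood, each library left out, a replicate block, libraries thinned to the smallest total, all 9 libraries in 1 fit, and ES IP alone against input. After their share of the counts was seen, a fit without 4 rows related to ribosomal RNA was added. Whether numbers shared by the groups pair the libraries was checked from correlated deviations. Figures were drawn with matplotlib 3.10.9.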

Results

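RNA bound to tagged ribosomes of cortical endothelial cells, and total RNA of the same tissue, were measured in untreated adult mice of the Abcb1a-TRAP line ES3026 (Abcb1a-EGFP/Rpl10a). TRAP, translating ribosome affinity purification, uses a transgene in which regulatory sequence of Abcb1a, the gene of a drug efflux pump of brain endothelium, drives a fusion of green fluorescent protein to the ribosomal protein Rpl10a. Antibodies against the fluorescent protein then pull down tagged ribosomes with the mRNA they carry. There were 9 libraries in 3 groups of 3. The immunoprecipitated (IP) libraries came from 2 investigators, known by the initials ES and JL, and the input libraries from JL alone; the submitters state that nothing else set these samples apart. The libraries held 43630000 ± 2370000 gene counts in the ES IPs, 34130000 ± 3200000 in the JL IPs and 44970000 ± 2010000 in the JL inputs (mean ± SD, n = 3 each). The deepest library held 46598478 and the shallowest 31987470. All levels below are CPM (normalised counts scaled to a common library size), as mean ± SD of the libraries of a group, n = 3, unless another n is given. Fold changes are on the log2 scale, with the standard error where one is given, and adjusted p-values come from edgeR's quasi-likelihood test. The labels do not say whether libraries of a group came from separate mice, so edgeR's p-values measure the spread between these libraries.

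The first comparison asked which RNAs the JL IPs enriched over the total RNA of the cortex. Endothelial genes were far higher in the IPs and neuronal genes lower. Abcb1a, on chromosome 5 at 8660077 to 8748575 in mm10, stood at 466 ± 21.5 CPM in the JL IPs and 2.16 ± 0.484 in the inputs, a log2 fold change of 7.75 ± 0.16 (adjusted p = 2.41e-09). Cldn5, the main claudin of brain endothelial tight junctions (chromosome 16, 18776847 to 18778262), stood at 543 ± 44.4 against 0.744 ± 0.353 CPM, a log2 fold change of 9.49 ± 0.24. Snap25, a synaptic SNARE protein of neurons (chromosome 2, 136713453 to 136782428), stood at 1373 ± 176 CPM in the IPs and 10500 ± 488 in the inputs, a log2 fold change of -2.93 ± 0.10. Of 17357 genes tested, 6372 were higher in the JL IPs and 6487 lower, of which 4176 and 5016 differed by at least 2-fold.

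Of the 10 largest increases, 1 was a row named by a sequence accession with no gene symbol. The 10 largest with a symbol were Tbx1, Cldn5, Ly6c1, Ctla2a, Cytl1, Pglyrp1, Slc52a3, Ly6a, Foxf1 and Foxq1, with log2 fold changes from 9.60 to 8.89; the extension to rows with a symbol was chosen after the values were seen. Tbx1, a T-box transcription factor, stood at 23.6 ± 3.79 CPM in the JL IPs and 0.0271 ± 0.0111 in the inputs, where its 3 libraries together held 4 counts. Ly6a and Ly6c1, surface proteins of the Ly6 family, reached 1421 ± 62.3 and 1053 ± 148 CPM. Slc52a3, a riboflavin transporter, stood at 143 ± 14.9 CPM against 0.276 ± 0.108. Foxf1 and Foxq1, forkhead transcription factors, stood at 77.2 ± 6.92 and 233 ± 18.1 CPM in the IPs and below 0.5 CPM in the inputs.

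All 32 pan-endothelial genes were higher in the JL IPs, with a median fold of 152. Ptprb, the vascular endothelial receptor phosphatase, stood at 1468 ± 137 CPM against 10.6 ± 2.20, Sox18 had the largest change of the list (8.76 ± 0.13) and Rasip1 the smallest (4.02 ± 0.12). Of 27 blood-brain barrier transporters, 26 were higher, with a median log2 fold change of 5.20. Slc2a1, the glucose transporter of the barrier, stood at 2983 ± 340 CPM against 33.2 ± 0.418, and Slc38a5, an amino acid transporter, rose most (8.44 ± 0.18). The exception was Lrp8, a reelin receptor, at 88.5 ± 10.4 against 92.2 ± 6.56 CPM (adjusted p = 0.611). All 18 genes of Wnt and Norrin signalling were higher, from Foxq1 (8.89 ± 0.15) to the co-receptor Lrp6 (0.69 ± 0.07), with a median of 5.13; Apcdd1, a Wnt inhibitor, stood at 419 ± 27.3 against 6.03 ± 0.773 CPM. All 14 interferon response genes were higher, with a median of 6.41, led by Ifi44 (8.11 ± 0.30); Ifitm3, which restricts viral entry, stood at 1604 ± 109 against 8.96 ± 1.68 CPM. Of 12 basement membrane genes 11 were higher, among them Sparc (4.27 ± 0.10) and perlecan, Hspg2 (5.73 ± 0.16), and the laminin chain Lamb1 was lower (-1.40 ± 0.17). With camera these 5 lists were called at a preset correlation and held with an estimated correlation, at adjusted p = 0.00328 for pan-endothelial genes, 0.0252 for transporters, 0.00328 for Wnt and Norrin signalling, 0.0331 for interferon response and 0.0423 for basement membrane.

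Genes of tight junctions and of vessel types were mostly higher too. Of 13 tight junction genes, 10 were higher, among them the scaffold Tjp1 (3.09 ± 0.08), and Cldn1, Cgn and Cldn12 were lower (adjusted p = 0.0534 for the list with an estimated correlation); the call of Cgn ended without input replicate 1 (adjusted p = 0.0542). All 14 arterial genes were higher (adjusted p = 0.0919 with an estimated correlation), from the gap junction protein Gja5 (8.49 ± 0.31) to the ligand Efnb2 (0.91 ± 0.10); Mgp, an inhibitor of calcification, stood at 1660 ± 244 CPM against 22.7 ± 5.43. Of 11 tested genes of veins and leukocyte adhesion, 10 were higher (adjusted p = 0.233 with an estimated correlation), among them Vwf at 177 ± 60.4 CPM against 0.631 ± 0.398, and Ackr1 was lower (-0.54 ± 0.12). Ackr1 shares exon sequence with Cadm3 on the same strand, so its reads could not all be assigned. Of 9 tested genes of peripheral or fenestrated endothelium, 4 were higher, among them Stab1 (2.59 ± 0.28), 2 were lower, among them Prox1 (-2.32 ± 0.14), and 3 did not pass. This list was not called by camera (adjusted p = 0.93).

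Genes of other brain cells were mostly lower in the JL IPs. All 17 neuron genes were lower, with a median log2 fold change of -2.65, from the dendritic protein Map2 (-3.79 ± 0.18) to the neurofilament Nefl (-1.50 ± 0.07). All 12 excitatory neuron genes and 14 of 15 inhibitory ones were lower, such as the kinase subunit Camk2a (-2.60 ± 0.22), Rorb (-3.20 ± 0.09) and the GABA-synthesising enzyme Gad2 (-3.21 ± 0.15); Lhx6 did not pass (0.20 ± 0.11, adjusted p = 0.124). With an estimated correlation the adjusted p was 0.115 for neurons, 0.0713 for excitatory and 0.0919 for inhibitory neurons. Of 17 oligodendrocyte genes 14 were lower, including Ermn (-3.50 ± 0.12), while Mal (0.77 ± 0.07) and Cldn11 (0.59 ± 0.15) were higher, Cldn11 not with upper quartile scaling (adjusted p = 0.0664) or library size alone (adjusted p = 0.0914). Of 12 precursor genes 9 were lower, including Olig1 (-2.75 ± 0.16), and of 20 microglia genes 16 were lower, including P2ry12 (-2.67 ± 0.36) and Itgam (-3.68 ± 0.64). The adjusted p with an estimated correlation was 0.215 for both oligodendrocyte lists and 0.115 for microglia. Of 20 astrocyte genes 16 were lower, such as the glutamate transporter Slc1a2 (-2.93 ± 0.18), and 4 were higher, among them glutamine synthetase, Glul (1.86 ± 0.07; adjusted p = 0.47 for the list with an estimated correlation). Of 9 choroid plexus and ependyma genes 7 were lower, led by Ttr, the thyroxine carrier (-3.77 ± 0.14; adjusted p = 0.214 for the list with an estimated correlation).

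Mural cell and fibroblast lists went both ways and were not called by camera, though fry, a rotation test, called pericytes (adjusted p = 0.0256), smooth muscle (0.00402) and fibroblasts (0.00758). Of 14 pericyte genes 2 were higher, with Anpep at 3.76 ± 0.29, and 8 lower; of 14 smooth muscle genes 6 were higher, such as Mylk (2.37 ± 0.10), and 4 lower; of 11 fibroblast genes 6 were higher, such as Islr (3.66 ± 0.25) and Dcn (1.28 ± 0.14), and 4 lower. Islr shares exon sequence with Islr2. Of 6 blood cell genes 1 was higher and 3 lower, including the globin Hbb-bs (-2.46 ± 0.50), and of 10 cell cycle genes 2 were higher and 8 did not pass. The adjusted p was 0.446 for pericytes, 0.477 for smooth muscle, 0.446 for fibroblasts, 0.549 for blood cells and 0.93 for cell cycle.

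Noncoding RNAs that stay in the nucleus were lower, and genes of the ribosome were modestly higher. The nuclear-retained list had a median log2 fold change of -2.93, near the -2.65 of neuron genes. Depletion beyond that of neuronal RNA was therefore not shown. Of 9 nuclear-retained RNAs 8 were lower, with Malat1 at 3803 ± 578 CPM against 21730 ± 1140, Meg3 at -3.12 ± 0.12 and Neat1 at -3.96 ± 0.19 (adjusted p = 0.0981 for the list with an estimated correlation). Of 82 cytosolic ribosomal protein genes 56 were higher and 3 lower, with a median log2 fold change of 1.03 (adjusted p = 0.472 with an estimated correlation); Rpl4 changed by 0.37 ± 0.07 and Rpl15 by -0.93 ± 0.10. The call of Rpl4 ended with upper quartile scaling (adjusted p = 0.153), library size alone (adjusted p = 0.171) and all 9 libraries in 1 fit (adjusted p = 0.124). Rpl10a, the gene of the tagged protein (chromosome 17, 28328471 to 28331033), did not pass, at 9.83 ± 0.825 against 7.60 ± 0.344 CPM (adjusted p = 0.0615). Ribosomal protein genes have many near-identical pseudogene copies, and reads that fit several places were not counted, so these values are uncertain. Of 78 nuclear genes of oxidative phosphorylation 42 were higher and 16 lower, including the ATP synthase subunit Atp5b (-1.04 ± 0.08), and the list was not called by camera (adjusted p = 0.197). Of 21 immediate early and stress genes 13 were higher, led by Klf2, a flow-responsive factor (8.42 ± 0.19), with Klf6 at 2.63 ± 0.14, and 5 were lower, including Egr1 (-1.50 ± 0.25) and Arc (-2.09 ± 0.12; adjusted p = 0.236 for the list with an estimated correlation).

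Of the 10 largest decreases 7 were rows named by accession. The 10 largest with a symbol were Ccbe1, Neat1, Tac2, Lgr5, Map2, Cntnap5b, Ttr, Dlx6os1, Smim18 and Scg2, with log2 fold changes from -4.17 to -3.66. In this comparison all 3 libraries of one group lay above all 3 of the other for 80.8% of tested genes, where chance gives 10%.

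**Figure D1:**
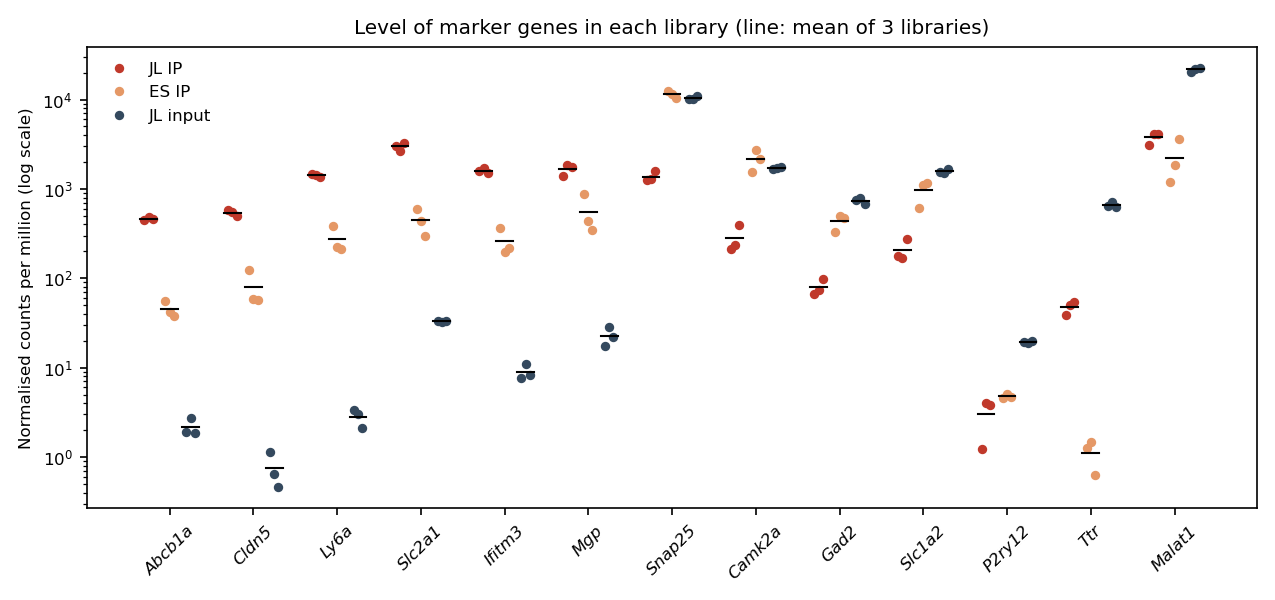
Normalised CPM (log axis) of 13 marker genes in each of the 9 libraries, with a black line at the mean of each group of 3. Abcb1a averaged 466 in the JL IPs, 44.9 in the ES IPs and 2.16 in the inputs, and Snap25 averaged 1373, 11450 and 10500.

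**Figure D2:**
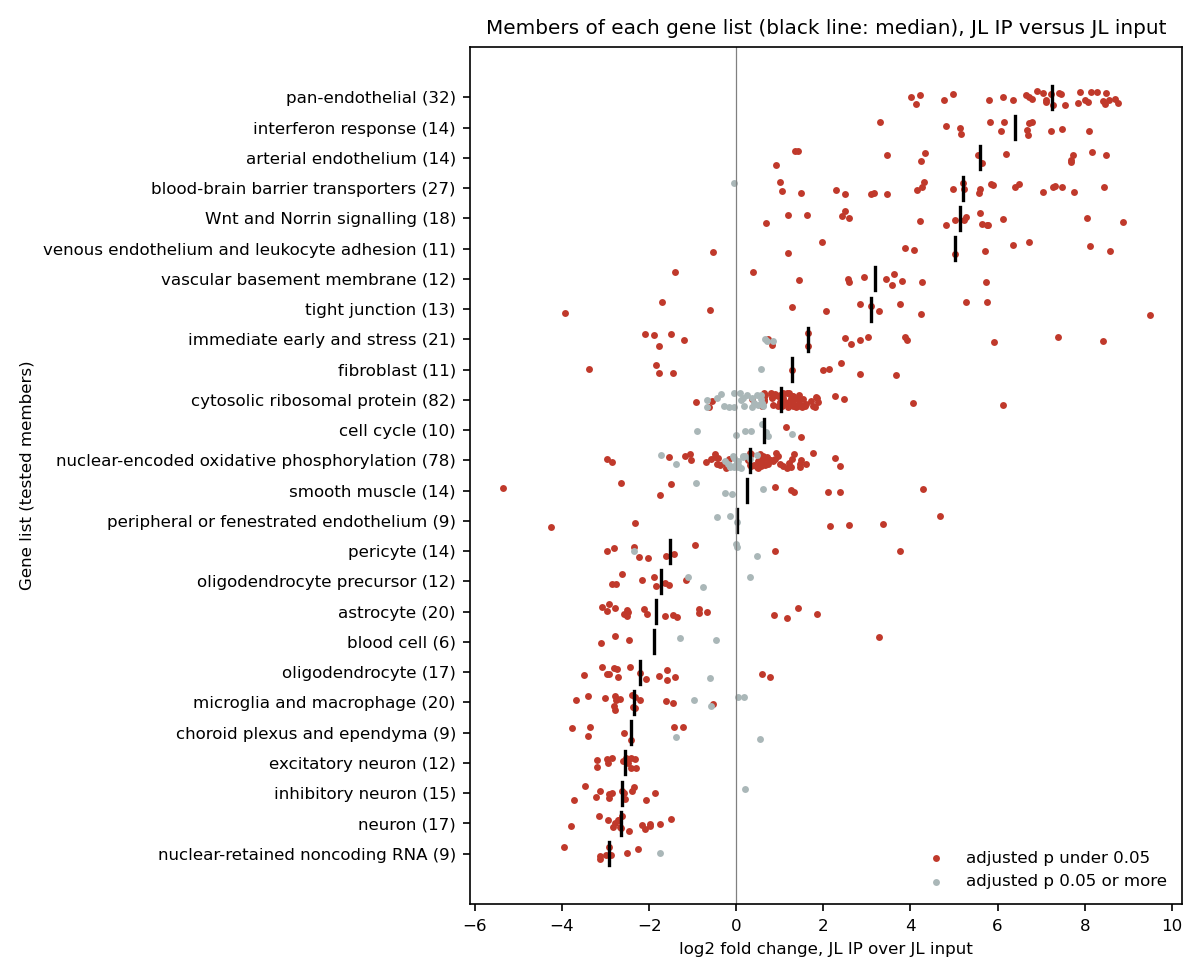
Log2 fold change, JL IP over JL input, of the tested members of each gene list, 1 point per gene, red where the adjusted p was under 0.05 and grey otherwise, with a black line at the list median. The pan-endothelial list has the highest median, 7.25, and the nuclear-retained RNAs the lowest, -2.93.

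The second comparison set the ES IPs against the JL IPs, the same fraction of the same line extracted by 2 people. Endothelial genes were lower in the ES IPs and neuronal genes higher. Abcb1a stood at 44.9 ± 9.21 CPM in the ES IPs and 466 ± 21.5 in the JL IPs, a log2 fold change of -3.30 ± 0.19 (adjusted p = 7.29e-07). Snap25 stood at 11450 ± 976 against 1373 ± 176 CPM, a log2 fold change of 3.14 ± 0.19. Of 16212 genes tested, 4809 were higher in the ES IPs and 4572 lower. All 3 ES libraries were sequenced in 1 lane and the JL libraries in 3 others, and there was no ES input, so lane and investigator cannot be told apart from the groups. Ddx3y, on the Y chromosome, had 660, 1037 and 855 counts in the ES IPs and 2298, 1 and 0 in the JL IPs. The mice behind the 2 sets may therefore differ in sex too, and this cannot be told apart either.

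All 32 pan-endothelial genes were lower in the ES IPs, with a median log2 fold change of -2.80, from Adgrl4 (-3.43 ± 0.22) to Ecscr (-1.96 ± 0.31). Of 27 barrier transporters 26 were lower, such as Slc2a1 at 446 ± 151 against 2983 ± 340 CPM and the thiamine transporter Slc19a3 (-3.70 ± 0.19), and Lrp8 did not pass (adjusted p = 0.832). Of 18 Wnt and Norrin genes 17 were lower, including Apcdd1 (-3.30 ± 0.21), and beta-catenin, Ctnnb1, did not pass (adjusted p = 0.214). Of 12 basement membrane genes 11 were lower, such as Sparc (-3.06 ± 0.19) and Nid1 (-3.66 ± 0.27). All 14 interferon response genes were lower, such as Ifitm3 (-2.54 ± 0.25), Oasl2 (-3.31 ± 0.19) and Ifi44 (-3.90 ± 0.25). Of 13 tight junction genes 10 were lower and 2 higher, with Cldn5 at -2.69 ± 0.29 and Jam2 at -2.85 ± 0.21. Of 14 arterial genes 12 were lower, including Mgp (-1.52 ± 0.30) but not Efnb2 (adjusted p = 0.747), and of 11 venous and adhesion genes 10 were lower, including Vwf (-2.16 ± 0.27) and Lcn2 (-3.70 ± 0.62). With an estimated correlation, camera's call held for Wnt and Norrin signalling (adjusted p = 0.0177) and basement membrane (adjusted p = 0.048). The other adjusted p-values with an estimated correlation were 0.0766 for pan-endothelial genes, transporters and tight junctions, 0.165 for interferon response, 0.214 for arterial and 0.21 for venous genes.

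All 17 neuron genes were higher in the ES IPs, with a median log2 fold change of 2.75, the largest change being that of the enolase Eno2 (4.17 ± 0.19). All 12 excitatory neuron genes were higher, including Camk2a (3.01 ± 0.30) and Tbr1 (3.52 ± 0.27). Of 15 inhibitory neuron genes 14 were higher, including Gad2 (2.54 ± 0.23) and the neuropeptide Vip (4.12 ± 0.47), and Lhx6 did not pass (adjusted p = 0.936). Of 20 astrocyte genes 12 were higher, including Aldh1l1 (3.25 ± 0.22) and Slc1a2 (2.31 ± 0.29), and 3 lower, including Glul (-0.96 ± 0.18). Of 17 oligodendrocyte genes 12 were higher, including Ermn (2.41 ± 0.19), and 2 lower, including Mal (-1.49 ± 0.20). With an estimated correlation the adjusted p was 0.0766 for neurons, 0.101 for excitatory neurons, 0.0766 for inhibitory neurons, 0.491 for astrocytes and 0.402 for oligodendrocytes. Of 20 microglia genes 10 were higher, such as Itgam (3.33 ± 0.70); of 12 precursor genes 7 were higher.

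Lists that camera did not call in this comparison included members that changed. Of 21 immediate early and stress genes 8 were higher, led by Egr2 (4.24 ± 0.24), with Egr1 at 2.35 ± 0.27, and 7 lower, including Klf4 (-1.97 ± 0.20) and Klf2 (-1.43 ± 0.23). Of 9 nuclear-retained RNAs 4 were higher and 1 lower. Malat1 stood at 2205 ± 1230 against 3803 ± 578 CPM (adjusted p = 0.0994) and Meg3 at 413 ± 169 against 330 ± 50.7 (adjusted p = 0.221). Malat1 was called lower with a replicate block (adjusted p = 0.0101), limma-voom (0.0368), the 3-group fit (0.0441) and without ES replicate 3 (0.00089). Meg3 was called higher without ES replicate 1 (0.022). Of 81 ribosomal protein genes 4 were higher, including Rpl15 (2.58 ± 0.29), 14 were lower and 63 did not pass. Without ES replicate 1 the median of this list moved from -0.24 to -0.60, and camera called it (adjusted p = 0.00988). Of 76 oxidative phosphorylation genes 19 were higher, including Atp5a1 (1.71 ± 0.17), and 8 lower. Their median turned from 0.12 to -0.26 without ES replicate 1, with no call by camera (adjusted p = 0.146). Of 7 choroid plexus and ependyma genes 2 were higher, with Foxj1 at 2.05 ± 0.40, and 3 lower, with Ttr at -5.35 ± 0.32. Of 13 pericyte genes 4 were higher and 3 lower, of 13 smooth muscle genes 2 and 5, of 11 fibroblast genes 3 and 6, of 7 peripheral endothelium genes 1 and 3, of 8 cell cycle genes 0 and 5, and none of 5 blood cell genes passed. The adjusted p of these lists with the preset correlation lay between 0.133 and 0.988. Rpl10a was lower in the ES IPs, at 4.39 ± 2.34 against 9.83 ± 0.825 CPM (adjusted p = 0.0197), a call that ended without ES replicate 2 (adjusted p = 0.0843) or 3 (adjusted p = 0.0799).

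The largest increases in the ES IPs with a gene symbol were Serpina3n, Neat1, Map3k9, Ctnna2, Tnnc1, Coro1a, Pla2g4e, Cplx3, Dcaf12l1 and Dclk3, with log2 fold changes from 5.43 to 4.26. Map3k9, a kinase of stress signalling (chromosome 12, 81721010 to 81781175), stood at 382 ± 172 against 15.2 ± 4.85 CPM, and Ctnna2, the neuronal alpha-catenin, changed by 4.50 ± 0.27. The largest decreases with a symbol were Oxt, Ttr, Yeats2, Itga6, Serpina3g, Lpar6, Ifi44, Cyyr1, B3gnt3 and Il2rg, with log2 fold changes from -7.30 to -3.75. Oxt, the oxytocin precursor (chromosome 2, 130576173 to 130577054), stood at 0.105 ± 0.0303 against 18.2 ± 13.4 CPM, and Ttr (chromosome 18, 20665280 to 20674321) at 1.11 ± 0.431 against 48.1 ± 8.45. Yeats2, a chromatin reader (chromosome 16, 20141063 to 20232573), stood at 52.0 ± 3.26 against 1677 ± 115 CPM. Among the first 10 in each direction, 3 increases and 2 decreases were rows named by accession.

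**Figure D3:**
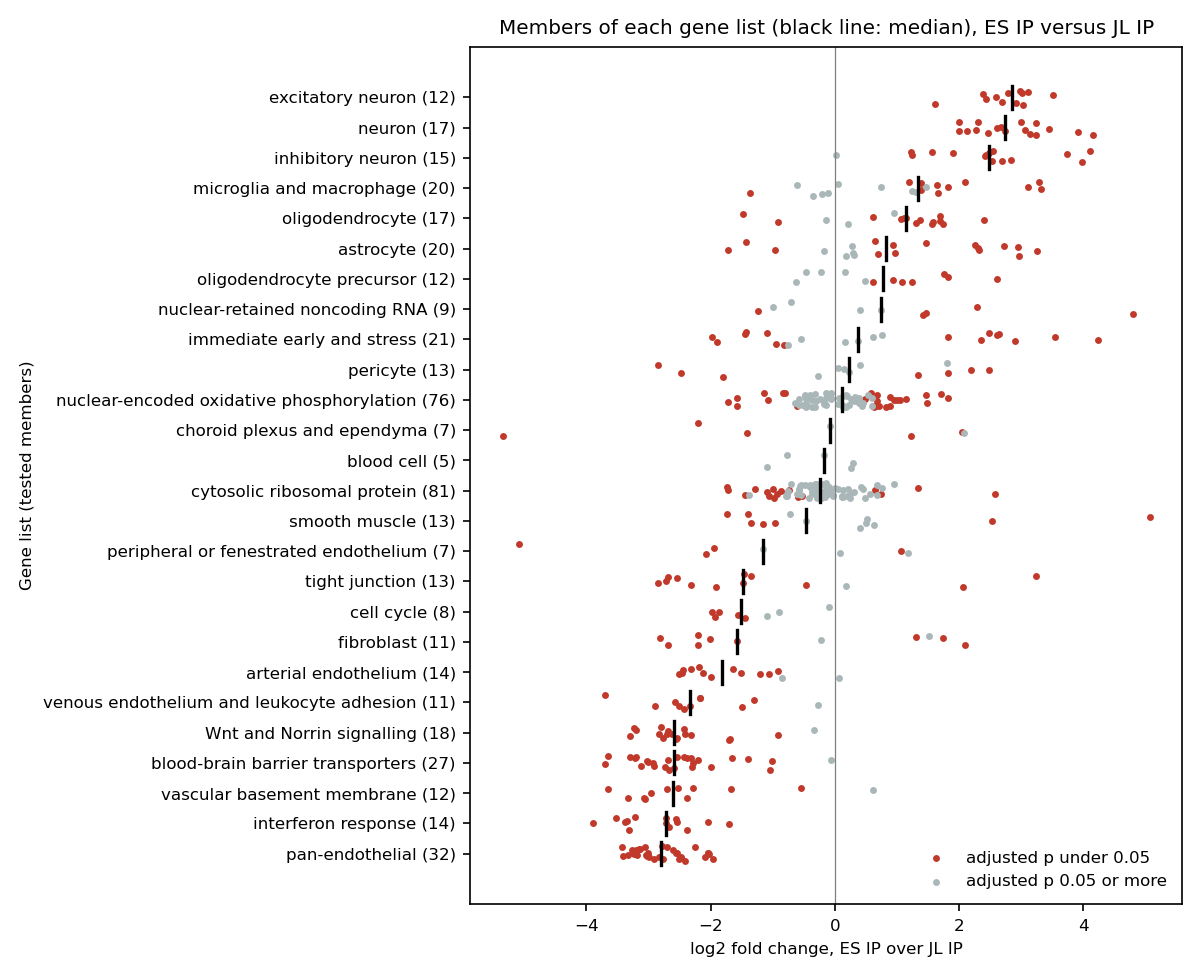
Log2 fold change, ES IP over JL IP, of the tested members of each gene list, 1 point per gene, red where the adjusted p was under 0.05 and grey otherwise, with a black line at the list median. Medians run from -2.80 for pan-endothelial genes to 2.86 for excitatory neuron genes.

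**Figure D4:**
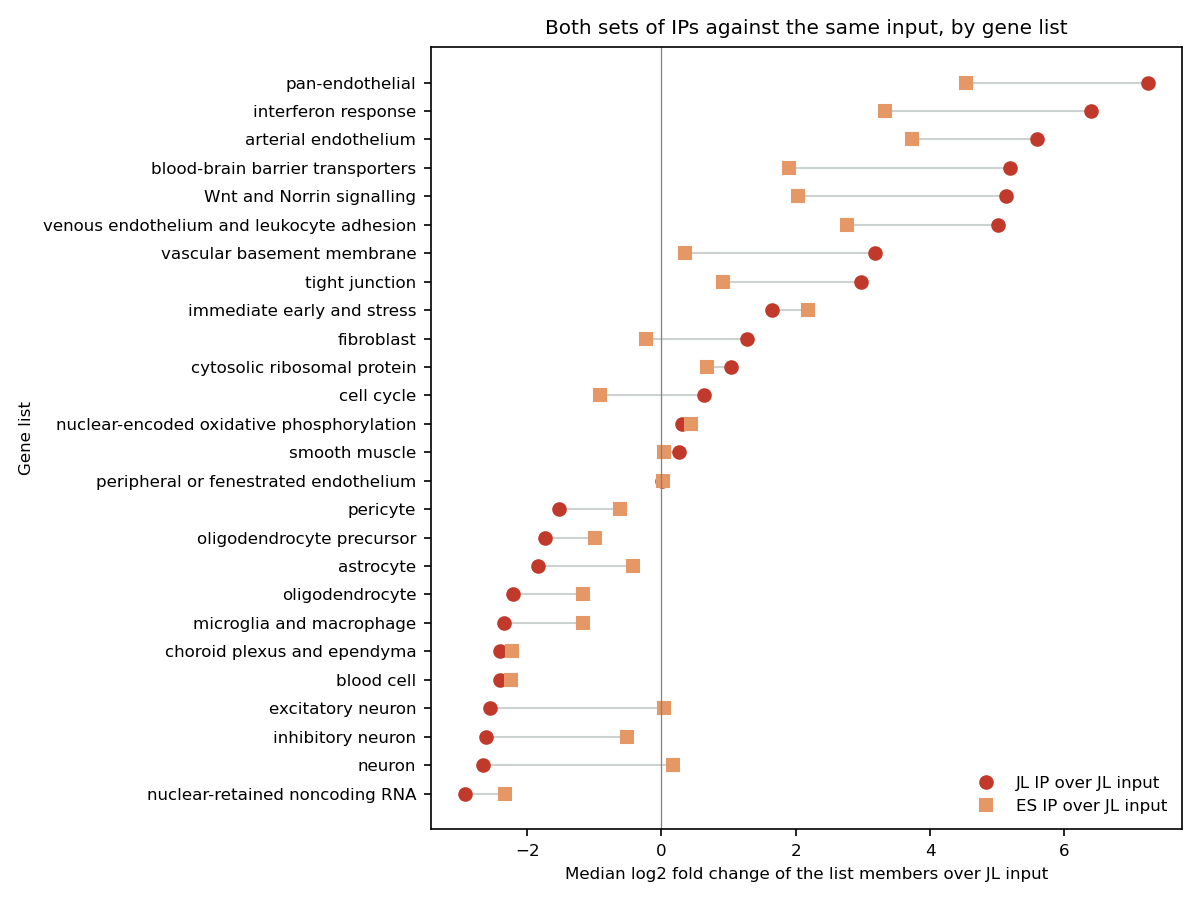
Median log2 fold change over JL input of each gene list, circles for the JL IPs and squares for the ES IPs, from 1 fit of all 9 libraries. Pan-endothelial genes had medians of 7.25 and 4.54, and neuron genes -2.65 and 0.17.

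The third comparison pooled the 6 IP libraries against the 3 inputs, since the submitters treat the IPs as equivalent. By camera at the preset correlation pan-endothelial genes were higher and oligodendrocyte, nuclear-retained and choroid plexus genes lower, while the neuron list was not called. None of these calls held with an estimated correlation, at adjusted p = 0.306, 0.303, 0.109 and 0.0562. Cldn5 stood at 311 ± 256 CPM over the IPs (n = 6) and 0.744 ± 0.353 in the inputs, a log2 fold change of 8.70 ± 1.26 (adjusted p = 0.00314), and Abcb1a at 255 ± 231 against 2.16 ± 0.484, a log2 fold change of 6.89 ± 1.28 (adjusted p = 0.00639). Of 17801 genes tested, 2991 were higher and 1990 lower. All 9 libraries in a 3-group fit gave 5464 and 5974, ES IP alone against input 4704 and 4422, and DESeq2 3972 and 3122. A replicate block gave fewer, 1529 higher and 1091 lower. The split was 60.0% higher among calls, 47.3% with upper quartile scaling and 49.6% with library size alone.

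The 5 largest increases were Tbx1, Cldn5, Ctla2a, Ly6c1 and Cytl1, from 8.78 to 8.54. The 5 largest decreases with a symbol were Ttr, the prolactin receptor Prlr, Snhg11, Trank1 and Lgr5, from -4.74 to -3.06. Over all rows, 4 of the 5 largest decreases were named by accession. In the 3-group fit Ttr changed over input by -3.77 in the JL IPs and -9.2 in the ES IPs. Its pooled value thus describes neither set of IPs. All 32 pan-endothelial genes were higher, including Ptprb (6.26 ± 1.21) and Sox18 (7.92 ± 1.25), as were 22 of 27 transporters, 14 of 18 Wnt and Norrin genes, 12 of 14 arterial genes such as Mgp (5.61 ± 0.75) and Gja5 (7.72 ± 1.12), 9 of 11 venous and adhesion genes, 9 of 14 tight junction genes, 4 of 12 basement membrane genes and all 14 interferon response genes. Of 21 immediate early and stress genes 14 were higher and none lower, including Klf2 (7.86 ± 0.75) and Klf6 (2.06 ± 0.52) but not Egr1 (0.03 ± 0.66, adjusted p = 0.976). In the JL IPs alone 5 of these genes were lower than input, Egr1 among them. With ES IP alone against input Egr1 was higher (0.76, adjusted p = 0.00267 by edgeR's test), so its pooled value describes neither set of IPs. Of 82 ribosomal protein genes 37 were higher, but not Rpl4 (adjusted p = 0.369), and of 79 oxidative phosphorylation genes 10 were higher and 4 lower. Rpl10a did not pass (adjusted p = 0.884).

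Of 17 oligodendrocyte genes 13 were lower, including Mbp (-1.79 ± 0.51) and Opalin (-2.16 ± 0.41), as were 5 of 12 precursor genes, 7 of 20 microglia genes and 8 of 20 astrocyte genes, of which 2 others were higher. Of 9 nuclear-retained RNAs 6 were lower, including Malat1 (-2.86 ± 0.49) and Meg3 (-2.95 ± 0.31) but not Neat1 (-0.19 ± 1.17, adjusted p = 0.918). Neat1 changed over input by -3.96 ± 0.19 in the JL IPs alone and by 0.76 in the ES IPs alone (adjusted p = 0.203 by edgeR's test for the latter). Of 9 choroid plexus and ependyma genes 4 were lower, including Enpp2 (-1.51 ± 0.17), and of 7 blood cell genes 3. None of 17 neuron genes passed by edgeR's test, and 1 of 12 excitatory and 2 of 15 inhibitory neuron genes were lower. In the 3-group fit the neuron list had a median over input of -2.65 in the JL IPs and 0.17 in the ES IPs. The pooled result thus does not show that neuron genes were unchanged in each set. Camera called 20 of 27 lists with the preset correlation and none with an estimated one. The smallest adjusted p with an estimated correlation was 0.0562, for choroid plexus and for immediate early genes, and it was 0.306 for pan-endothelial genes. The lists of pericytes, smooth muscle, fibroblasts, cell cycle, peripheral endothelium, neurons and sex-linked genes were not called by camera, at adjusted p = 0.0511, 0.482, 0.639, 0.963, 0.914, 0.0611 and 0.639. Leaving out input replicate 1, 2 or 3 left 868, 916 or 859 genes higher and 664, 689 or 638 lower. Without any 1 input the calls of Ttr (adjusted p = 0.0654 to 0.0666), Mbp (0.0865 to 0.102) and Klf6 (0.0755 to 0.0832) ended, and that of Mbp also without JL IP replicate 3 (0.0565). A replicate block also ended the calls of Ttr, Mbp and Klf6 (adjusted p = 0.0646, 0.0764 and 0.0539). On simulated counts with this spread the test recovered 0% of 2-fold and 13% of 4-fold changes. Few genes were changed there, which makes the adjusted cutoff stricter than in the real data. These shares can thus understate recovery here, yet genes without a call could still have changed by such folds.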

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

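The tests of carried-over RNA, of a mixture, of immediate early genes and of choroid plexus markers in this part were chosen after the levels in the ES IPs had been seen; the counts over other splits were planned.

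The ES and the JL IP libraries differed in 13 gene lists by camera at the preset correlation. With an estimated correlation 2 of these held, Wnt and Norrin signalling (adjusted p = 0.0177) and basement membrane (adjusted p = 0.048); pan-endothelial genes and neurons were at 0.0766, astrocytes at 0.491 and oligodendrocytes at 0.402. The median log2 difference, ES minus JL, was -2.80 for pan-endothelial genes, -2.60 for barrier transporters, -1.47 for tight junctions, -2.59 for Wnt and Norrin signalling, -1.82 for arterial and -2.33 for venous genes, -2.61 for basement membrane and -2.71 for interferon response. It was 2.75 for neurons, 2.86 for excitatory and 2.49 for inhibitory neurons, 0.82 for astrocytes and 1.15 for oligodendrocytes. In data outside the gene rows, alignments counted as not unique came to 1.90 per gene count in the JL IPs and 1.13 in the ES IPs, above the 0.626 of the inputs.

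The ES IPs held more neuronal and less endothelial mRNA than the JL IPs. Total input RNA carried into them would bring nuclear RNA along with neuronal mRNA. But on a scale from 0 (JL IP) to 1 (input) the median of 8 nuclear-retained RNAs was 0.171 and that of 17 neuron genes 1.18. An exact permutation test of the difference in mean position, not in medians, gave a two-sided p = 0.00131. Single nuclear-retained RNAs ran from -0.0903 to 1.74, and neuron genes from 0.373 to 3.15. The highest nuclear-retained RNA was Neat1, at 46.3 ± 32.9 CPM in the ES IPs and 27.4 ± 4.47 in the inputs. Its mean on its own went the way such carryover predicts but past the input level, with a wide spread. Ribosome-bound RNA of all other cells carried alike could raise their lists alike. The log2 medians over input were 0.17 for neurons, -0.42 for astrocytes and -1.17 for both oligodendrocytes and microglia. Input was total rather than ribosome-bound RNA and came from JL alone, so unequal medians do not decide against such carryover. The gap between the extremes was 1.34 (permutation test, the 74 genes shuffled over all 4 lists, p = 0.00071). All genes came from the same libraries and were taken as independent in both permutation tests, so their p-values measure spread between genes. Sequencing lane, the mice used and extraction by another investigator stay open, since ES and JL libraries shared 0 lanes and no ES input was analysed. No biological explanation was tested, since the design names none.

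A mixture of RNA as in the JL IPs and RNA as in the input would put each ES level between those of the other groups. Of 17801 genes, 1311 were above both and 984 below both, 12.9% of those tested. Counts simulated for a mixture with 14% of JL IP RNA gave 0.103% of 17505 genes. The simulation held no difference in lane, investigator or mice between ES and JL libraries. Such a difference could also put genes outside the range, so these shares alone do not decide against a mixture. Other values argue against the simulated mixture, for the reads and RNAs they cover. The ambiguous share was 2.48 ± 0.0507% in the ES IPs, 2.09 ± 0.046% in the JL IPs and 10.8 ± 0.52% in the inputs. On the scale above, 8 nuclear-retained RNAs had a median position of 0.171, with single ones up to 1.74. A mixture with 14% of JL IP RNA would lie near the inputs in both. Of 21 immediate early and stress genes 9, or 42.9%, were above both, which lay between the bounds set for that test (5% for a mixture, 50% against it), so it did not decide for these genes. This narrower test was written first. The test over all genes replaced it after some levels of the ES IPs, those of Kalrn and Egr2 among them, had been seen; the narrower one was then restored, and both results are given.

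Ttr was lower in the ES IPs than in the JL IPs. If choroid plexus tissue in the JL dissections were the cause, its other markers would be lower too. Over the other 6 tested members of the choroid plexus and ependyma list, the median log2 fold change was 0.57. Its 95% bootstrap interval ran from -1.80 to 2.06. The list mixes markers of choroid plexus and of ependyma. Of its 7 tested members, Ttr included, 3 were lower and 2 higher. The test therefore leaves this open.

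For JL IP against input, 1 of 10 splits of the 6 libraries gave as many genes as the real 12859, the real split itself, and the highest other gave 0; for ES against JL IP the real split gave 9381 and the highest other 0. With 10 splits each, these are too few for a share under 0.05. For all IP against input, 2 of 84 splits gave at least the real 4981 genes, a share under 0.05. The median over the other splits was 0, so any grouping that keeps the groups whole can have a small share. That share does not single out IP against input. The highest other, 10076 genes, set the JL IPs against the ES IPs with the inputs, which points to a structure of the samples.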

How the results depend on the processing

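The counts of genes for JL IP against input and for ES against JL IP stayed within 1.5 times under every alternative. Without single libraries they ran from 5848 to 6571 higher and 5629 to 7130 lower for the first. For the second they ran from 4149 to 4910 and 3820 to 4994. For JL IP against input, upper quartile scaling gave 5425 higher and 7555 lower, and library size alone 5392 and 7566. The share higher among its calls was 49.6% in the main fit, 41.8% with upper quartile scaling and 41.6% with library size alone. The near-even split there thus depends on the scaling. For all IP against input the counts moved: 3122 lower with DESeq2, 5464 higher and 5974 lower with all 9 libraries in a 3-group fit, 4704 and 4422 with ES IP alone, and 859 to 3524 higher and 638 to 2183 lower without single libraries. Dropping an input leaves fewer samples in a group of 3; for the rest the cause was not tested. With a replicate block the counts were 6124 and 6307 for JL IP against input, 4771 and 4532 for ES against JL IP, and 1529 and 1091 for all IP against input, where the block ended the calls of Ttr, Mbp and Klf6 (adjusted p = 0.0646, 0.0764 and 0.0539), as did leaving out any 1 input. Deviations of JL IP and input libraries of the same number correlated at 0.0998, 0.0382 and 0.0593, each the best match of its JL IP. Libraries of the same number also shared a lane, and Y-linked counts were high in number 1 and near 0 in numbers 2 and 3 of both groups. These are hints from the data and lanes; the labels do not say what the number marks. The pan-endothelial list lost its call with an estimated correlation for ES against JL IP (median -2.80, adjusted p = 0.0766) and for all IP (6.47, adjusted p = 0.306). The alternative without mitochondrially encoded genes was not run, since these were not analysed here.

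Some calls were gained: for ES against JL IP, Malat1 with the replicate block (-0.85, adjusted p = 0.0101), limma-voom (0.0368), the 3-group fit (0.0441) and without ES replicate 3 (-1.24, 0.00089), Meg3 without ES replicate 1 (0.022) and Ctnnb1 without ES replicate 2 (0.0201); for JL IP against input, Lrp8 with upper quartile scaling (-0.31, 0.0179) and library size alone (-0.31, 0.0259) and Rpl10a with limma-voom (0.0492) and without JL IP replicate 3 (0.0455); for all IP, Neat1 in the 3-group fit (-1.60, 0.00185), Egr1 with ES IP alone (0.76, 0.00267), the neuron list without any 1 ES library (0.0174 to 0.0302) and pericytes with the block (0.0433) and without ES replicate 1 (0.0493), JL IP replicate 3 (0.0449) or input replicate 3 (0.0386). For ES against JL IP, ribosomal proteins gained a call without ES replicate 1 (-0.60, 0.00988) and fibroblasts without JL IP replicate 1 (0.0266). Fry also called, for JL IP against input, pericytes (0.0256), smooth muscle (0.00402), fibroblasts (0.00758), cell cycle (0.022) and oxidative phosphorylation (0.000609); for ES against JL IP, peripheral endothelium (0.00313), fibroblasts (0.0221), oligodendrocyte precursors (0.0132), microglia (0.00458), choroid plexus (0.00458) and cell cycle (0.00255); and for all IP pericytes (0.00331), but not basement membrane (0.219), excitatory (0.217) and inhibitory neurons (0.0922) and oxidative phosphorylation (0.29).

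Reversed values had no call in the main analysis, and the cause was not tested, except that the sex-linked list for ES against JL IP gained a call (adjusted p = 1.57e-05) without JL IP replicate 1, the only JL IP with more than 1 count of Ddx3y (2298, against 1 and 0). For JL IP against input these were Lhx6 (-0.06 with upper quartile scaling and with library size alone), Lrp8 (-0.15 to 0.01 without single libraries), the peripheral endothelium list (-0.04 with RLE, -0.24 with library size alone, -0.07 with the block, -0.17 to 1.24 without single libraries) and smooth muscle (-0.12 to 0.55 without single libraries). For ES against JL IP they were Lrp8 (0 with library size alone, -0.26 to 0.12 without single libraries), Efnb2 (-0.01 in the 3-group fit, -0.04 to 0.20), Lhx6 (-0.06 in the 3-group fit, -0.01 without ribosomal RNA-related entries, -0.02 to 0.10), and the lists of smooth muscle (-0.68 to 0.11), blood cells (-0.58 to 0.56), oxidative phosphorylation (-0.26 to 0.29) and sex-linked genes (3.65 with the block, -0.88 to 10.08). For all IP they were Egr1 (-0.13 with upper quartile scaling, -0.11 with library size alone, -0.03 with the CPM filter, -0.45 with limma-voom, -0.37 in the 3-group fit, -0.22 to 0.24), Neat1 (0.76 with ES IP alone, -1.13 to 0.06), Rpl10a (-0.30 to 0.07), cell cycle (-0.03 with RLE, -0.20 with library size alone, -0.01 with the block, -0.13 to 0.24) and sex-linked genes (2.82 with the block, -1.20 to 10.72).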

Other observations

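Gene families, grouped by symbol after the data had been seen, also separated JL IP from input. The genes named in this part were chosen after their values were seen. Of 16 families tested with Fisher's exact test against all other genes, 6 differed in their share of higher genes at an adjusted p under 0.05. Fisher's test took genes as independent, though all came from the same libraries. Its p-values thus compare genes and do not measure the spread between libraries. Of 30 Fox transcription factors 19 were higher and 6 lower (adjusted p = 0.0101), with Foxf2 at 8.04 ± 0.11, Foxc1 at 6.09 ± 0.12 and Foxc2 at 5.49 ± 0.19. Of 16 Notch pathway genes 12 were higher and 3 lower (adjusted p = 0.0101), including the ligand Dll4 (7.67 ± 0.22), Notch4 (5.42 ± 0.16) and Notch1 (2.73 ± 0.13). Of 22 TNF ligands and receptors 15 were higher and 4 lower (adjusted p = 0.0101), including Tnfsf10 (7.33 ± 0.36).

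The other 3 families were mostly lower in the JL IPs. Of 86 genes with symbols starting Kcn, taken as potassium channels, 71 were lower and 8 higher (adjusted p = 6.9e-08). Kcna1 stood at -2.02 ± 0.11, Kcnj10 at -2.87 ± 0.23 and Kcnq1 at 7.46 ± 0.32. This prefix also takes in genes that are not channels, such as the noncoding RNA Kcnq1ot1. Of 43 glutamate and GABA receptor subunits 40 were lower and 0 higher by edgeR's test (adjusted p = 4.14e-08), including Gria2 (-2.97 ± 0.16). Of 65 protocadherins 49 were lower and 2 higher (adjusted p = 2.03e-09), with Pcdh12 at 7.89 ± 0.59 and Pcdh9 at -2.68 ± 0.08. The medians of all 6 families kept their sign with RLE factors, upper quartile scaling and library size alone.

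Some genes were higher in the ES IPs than in both other groups. Kalrn, a neuronal exchange factor, stood at 8305 ± 843 CPM in the ES IPs, 1946 ± 236 in the JL IPs and 370 ± 3.21 in the inputs; it was picked out after its values were seen. Egr2 stood at 100 ± 7.78, 5.61 ± 1.68 and 19.3 ± 3.95 CPM, and Junb at 56.7 ± 23.9, 16.9 ± 0.658 and 10.2 ± 0.626. Were the JL IPs purely endothelial, the median 152-fold enrichment of pan-endothelial genes would correspond to 0.658% of the input mRNA. Over the 32 genes the folds ran from 16.2 to 434, and the share from 6.16% to 0.230%. Neuron genes, however, kept a median of 0.159 of their input level in the JL IPs. Input was also total rather than ribosome-bound RNA, so these shares do not estimate the endothelial part of the cortex.

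The sex-linked genes differed between libraries of a group. Ddx3y, on the Y chromosome, had 2298 counts in JL IP replicate 1 and 3249 in input replicate 1, and at most 1 count in replicates 2 and 3 of either group. The ES IPs had 660, 1037 and 855. Xist had 1, 986 and 1156 counts in input replicates 1, 2 and 3, 51, 196 and 177 in the JL IPs and 35, 181 and 68 in the ES IPs. Each ES IP, and JL IP replicate 1, thus held both Y-linked and Xist counts.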
